A study of Salmo salar with 48 samples.

How the data were processed

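Total RNA from Atlantic salmon skin was labelled with Cy3 and hybridised to 48 one-colour Agilent arrays, 1 array per fish. Fish were held under 3 temperature regimes, called T12 (constant 12 °C), F (fluctuating between 12 and 17 °C) and H (constant 17 °C), and were sampled before the trial (T0, 4 fish per regime) and at 2 later time points (P1 and P2, 6 fish per regime each). Per the labels the replicates are separate fish. Each regime had 2 tanks, and the tank of each fish, 8 arrays per tank over the 3 samplings, was taken from the number at the end of its array's file name.

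Per the file headers, each array's deposited scanner table gives the processed signal as an intensity that had been background-subtracted within the array and not normalised between arrays, with the median pixel intensity of the spot and of its local background beside it. Other columns of these deposited files are flags of 0 or 1 and a control type. The submitters' processing notes name Agilent Feature Extraction as the software. The authors' value table of the whole series, also deposited, holds an intensity per probe and array with no description of how it was made. Set against the scanner columns, it equalled the spot median minus the local background median times 1 factor per array, and the totals of the listed spots of an array lay between 2.65664e+07 and 2.69295e+07. It listed between 26589 and 39829 spots per array, so the scanner's processed signal was analysed and the authors' table was kept as an alternative.

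The 42386 probes that were not controls were put on the log2 scale and each array's 75th percentile was subtracted, so every level below is a log2 intensity relative to that percentile. A probe was kept if it was well above background, by the scanner's flag, in a share of at least 0.5 of the arrays of any group, which left 33859 probes. Spots flagged as uneven were treated as missing. Probes carry RefSeq accessions, of which 25641 matched 1 gene each in the RefSeq name table of assembly Ssal_v3.1 (60.5% of the probes), 8155 with a gene symbol (19.2%) and 17486 with a LOC name alone. No coordinates are given, since the build behind the array is not stated. Named genes are therefore a subset of the called probes. No named gene had another probe of the same gene identifier among those kept, and entries of the same enzyme under another symbol were not sought.

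All 48 arrays entered 1 fit of 9 group means with limma 3.58.1 in R 4.3.3, with the data.table package in version 1.17.8 and statmod 1.5.0. Moderated statistics used the intensity trend and robust settings, with 39 residual and a median of 3.82 prior degrees of freedom. There were 13 contrasts: H against T12, F against T12 and H against F at each of T0, P1 and P2; P1 against T0 and P2 against P1 within T12; and the change from P1 to P2 in H and in F minus that in T12. A probe was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over the probes of its contrast, and "rose" or "fell" is used of called probes alone. Errors beside log2 differences are standard errors of the fit, and p-values treat fish, not tanks, as the units.

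Before the data were examined, 32 gene lists for tissues, cell types and processes were fixed, and the 31 with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists of a contrast. Camera with a correlation estimated from the data and fry, a rotation test of whether a list's members move on balance 1 way, were run beside it. In all, 341 list tests were made over 11 contrasts. Lists can share genes, as the clock and glucocorticoid lists share per1b and the interferon and antigen presentation lists psmb8b. Calls of such lists are not separate results. The named genes follow a rule fixed at the same time. For each comparison of regimes at P1 and P2 it takes the 10 highest and 10 lowest log2 differences among called probes with a gene name. It adds the 3 members with the smallest p of each list called by camera, and takes 5 and 5 for the other contrasts. Hsp90aa1, hsp90ab1, hspa1b, hspa8, serpinh1a and cirbpb were always to be included. Hsp90aa1 had no probe under that symbol among those kept and is not reported. Where a gene's signal was not above background on any array of a group, the fold is given as a lower bound.

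The fit was tested on simulated data with the arrays' own spread, 50 probes at each of 4 log2 changes among 33859 probes. The noise was independent between probes and equal in spread in all groups, with no outlying array and no slide, tank or day effect. The recovery and the shares of false calls therefore need not hold for the real arrays. For H against T12 at P1 it recovered 22 of 50 probes changed by 1 and 42 of 50 changed by 2, with 4 false among 125 calls. For F against T12 at P1 it recovered 23 and 42 of 50 with 9 false among 120 calls, and for H against F at P1 22 and 42 of 50 with 8 false among 130. For H against T12 at P2 it recovered 28 and 38 of 50 with 4 false among 120, for F against T12 at P2 27 and 37 of 50 with 9 false among 125, and for H against F at P2 16 and 37 of 50 with 4 false among 107. The false calls came to 7.5% and 7.2% of all calls for F against T12 at P1 and P2.

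Alternatives fixed beforehand were quantile normalisation, normexp background correction with an offset of 50, both filters on dim probes, the authors' table, array weights, a fit to the compared groups alone, tank, slide and fish number as blocks, other thresholds, subtraction of the difference at T0, the T12 fish split in a pair of sets so that the H and F comparisons share none, and leaving out each array in turn. The normexp alternative used the spot medians, since the files hold no spot means. Chosen after the data were seen were normexp followed by quantile normalisation, means per tank as the units, the scan day as a block, leaving out F_P1 fish 6, and leaving out T12_P2 fish 2 and 6.

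Scan days were read from the file headers and are numbered here. Day 1 held all T0 and T12_P1 arrays and 5 of the 6 F_P1 arrays, day 2 the 6 H_P1 arrays alone, and day 3 all P2 arrays and F_P1 fish 6. The H comparisons at P1 and the day therefore cannot be told apart, the comparisons at T0 and at P2 lie within 1 day, and P2 against P1 crosses days. Slides, read from the same headers, are numbered too. F and T12 arrays shared only slides 14 and 16 at P1, only 3 and 11 at P2, and none at T0. Slide 3 held T12_P2 fish 2. F_P1 fish 6 lay on slide 7 with P2 arrays, so the slide block takes it out of the comparison at P1. For F against T12 that block therefore rests in part on arrays of other groups. The labels do not say that fish of 1 number belong together, so the test was not paired, and the fish number as a block is among the alternatives. Performance measures of the fish are not analysed here.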

Results

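Gene expression was measured in the skin of post-smolt Atlantic salmon of about 50 g that were kept in 6 tanks of 900 L, 120 fish per tank and 720 in all. The tanks were first held at about 8 °C for 4 weeks and at 12 °C for 1 week. T12 tanks then stayed at 12 °C, the level called optimum in the labels. The other tanks were warmed by 1 °C per day to 17 °C, where H tanks remained, while F tanks were held there for 5 days, cooled over 5 days, held at 12 °C for 5 days and warmed again, in 3 rounds. Skin was taken from 4 fish per regime before the trial (T0) and from 6 fish per regime at each of 2 later samplings set by the temperature peaks (P1 and P2), which gave 48 arrays in 9 groups. The sample titles call these samplings first peak (P1) and second peak (P2) in each regime. The labels do not settle whether F tanks were then at 17 or at 12 °C. The question was how constant and fluctuating heat change skin relative to the optimum, and whether the 2 kinds of heat differ.

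Between 47.5% and 86.1% of an array's spots were well above background, the 75th percentile of the processed signal lay between 75.2 and 361, and no spot was saturated. The first principal components held 17.9% and 13.7% of the variance. Arrays correlated with the others at a median r of 0.951 across probes, which are not independent replicates. F_P1 fish 6 had the lowest median r, 0.854, and differed from its group's mean by more than 2 on the log2 scale at 4753 probes, against 2686 on the next array. Its 47 genes of motile cilia lay at a median of 3.63 above the other F_P1 arrays and its 42 trunk hox genes at −3.59, so counts that involve this fish are also given without it. T12_P2 fish 2 and fish 6 had liver marker scores of 7.80 and 5.26 and exocrine pancreas scores of 7.40 and 2.22, and lists of liver-made proteins are given with and without these 2 fish. Pancreas scores were also high in F_P2 fish 4 (3.72), T12_P2 fish 3 (3.23), H_P2 fish 3 (2.19) and F_P2 fish 5 and 1 (2.16 and 2.00), which were kept. The group means at P2 were 1.88 ± 3.16 (SD, n = 6) in T12, 1.59 ± 1.48 in F and 0.06 ± 1.39 in H.

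**Figure D1:**
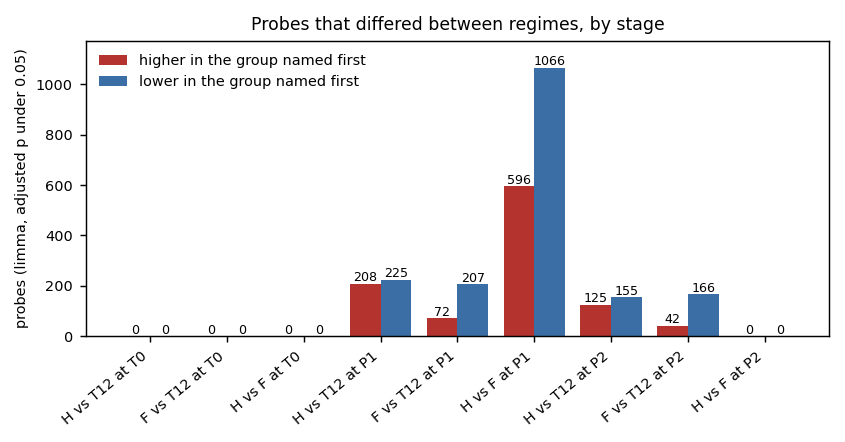
The bars show how many probes were called higher and lower in the group named first in each comparison by limma at an adjusted p under 0.05. At P1 the counts were 433 for H against T12, 279 for F against T12 and 1662 for H against F, and at P2 they were 280, 208 and 0.

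In skin from constant heat at P1, ciarta, cirbpb and fbxo32 were among the genes lower than at 12 °C and myom1b among those higher. The circadian repressor ciarta fell by 0.88 ± 0.19 on the log2 scale (adjusted p = 0.014, n = 6 and 6, lower in 6 of 6 fish than in any T12 fish). Cirbpb, a cold-inducible RNA-binding protein, fell by 0.62 ± 0.16 (adjusted p = 0.0434). The sarcomere M-band gene myom1b rose by 2.37 ± 0.50 (adjusted p = 0.00886), and ankfn1b by 1.88 ± 0.37 (adjusted p = 0.00486). Fbxo32, a ubiquitin ligase of muscle atrophy, fell by 1.34 ± 0.34 (adjusted p = 0.0364). Skeletal muscle genes lay above 0 in 19 of 22 cases beside them (median 0.48) without a call (camera adjusted p = 0.103), and had a median of 0.94 before the trial. Other steep falls were seen in arhgef37 (−2.09 ± 0.47), the melanosome transport gene mlphb (−1.46 ± 0.39), wars2 of mitochondrial tryptophan-tRNA charging (−1.14 ± 0.24) and apbp2 (−1.12 ± 0.18). Next came the cation channel trpc1 (−1.01 ± 0.24), glpk3 (−1.01 ± 0.24), the Golgi stacking gene gorasp1a (−0.99 ± 0.20), sema4d (−0.95 ± 0.20) and mast3b (−0.90 ± 0.24), with adjusted p from 0.000875 to 0.0492. The steepest rises were in hoxb8aa (3.07 ± 0.76), frrs1a (2.60 ± 0.67), glt1d1 (2.43 ± 0.60), pdrg1 (2.37 ± 0.54), map6d1 (1.86 ± 0.48) and prvt (1.65 ± 0.40). The transcriptional repressor helt was at least 2.53-fold and tyw3 at least 1.76-fold higher, since no T12 array had them above background.

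Among 17 interferon and antiviral genes at P1, none was called over all probes in H against T12, 8 rose when adjusted over the list alone, and 15 lay above 0 with a median of 0.43 (camera adjusted p = 1.29e-05; adjusted p = 0.509 with an estimated correlation). Members with the smallest p were stat2 (0.54 ± 0.15), irf3 (0.46) and isg15 (1.32 ± 0.50), the last pair standing at 0.25 and 0.61 without H_P1 fish 6. Of 34 genes of mitochondrial respiration 28 lay above 0 (median 0.17, camera adjusted p = 0.0116; adjusted p = 0.784 with an estimated correlation). Among them were ndufv1 (0.80 ± 0.22), cox6a1 (0.24) and sdhdb (0.28). Of 12 circadian clock genes 1 fell, 4 fell when adjusted over the list alone, and 9 lay below 0 (median −0.37, camera adjusted p = 0.0114, fry adjusted p = 0.00392; adjusted p = 0.357 with an estimated correlation). Bhlhe41 stood at −1.03 ± 0.29 and per1b at −2.13 ± 0.60 short of the threshold. Ribosomal proteins lay below 0 in 36 of 38 cases (median −0.22, camera adjusted p = 5.64e-05; adjusted p = 0.784 with an estimated correlation). Examples were rpl35 (−0.36), rpl17 (−0.42, or −0.25 without H_P1 fish 3) and rps28 (−0.40). Before the trial, with no heat, the interferon, mitochondrial and ribosomal medians of H against T12 were already 0.38, 0.69 and −0.20, each called by camera. None of 13 heat shock proteins was called (median 0.08, camera adjusted p = 0.878). Hsp90ab1 stood at 0.03, the inducible hspa1b at 0.70 ± 0.96 (0.095 without H_P1 fish 3), the constitutive hspa8 at −0.22 and the collagen chaperone serpinh1a at 0.08.

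Limma called 433 probes in H against T12 at P1, 208 higher and 225 lower, with 5345 at an unadjusted p under 0.05 where 1693 would be called by chance alone. The authors' table gave 132 higher and 68 lower. The count fell to 186 without H_P1 fish 5, 192 without T12_P1 fish 3, 200 without H_P1 fish 1, 227 without H_P1 fish 4 and 239 without T12_P1 fish 6. It rose to 841 without F_P1 fish 6. It was 4 after normexp background correction, where frrs1a (−0.0264), tyw3 (−0.10) and hspa1b (−0.14) changed sign, and 1 with means per tank as the units. Quantile normalisation gave 985, a fit to the compared arrays alone 155, and subtraction of the T0 difference 3. The H arrays were alone in their scan day. Of the genes named, myom1b, ankfn1b, wars2, apbp2, gorasp1a, sema4d and ciarta stayed under the threshold without any 1 of the 12 arrays. The other calls were lost without 1 to 10 of them, to adjusted p of 0.127 for cirbpb without H_P1 fish 1 and 0.143 for mlphb without H_P1 fish 5.

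Under fluctuating heat at P1, 207 of the 279 called probes were lower than at 12 °C, a balance that the authors' table turned (43 higher and 35 lower). The base excision repair gene unga fell by 1.01 ± 0.13 (adjusted p = 2.18e-05), apbp2 by 1.29 ± 0.18 (adjusted p = 5.99e-05) and cirbpb by 0.83 ± 0.16 (adjusted p = 0.00542). In unga and apbp2 all 6 F fish lay below every T12 fish. The nucleolar proteins npm and rsl1d1 fell by 1.38 ± 0.33 and 1.01 ± 0.25 (adjusted p = 0.0283 and 0.0338). Faub, a ribosomal protein precursor, fell by 0.63 ± 0.12 (adjusted p = 0.00457). Other steep falls were in tmem86a, yk005 (−1.36 ± 0.30), LOC100196055 with the synonym pigf (−1.13 ± 0.21), the valine-tRNA synthetase vars1 (−1.08 ± 0.27) and glpk3 (−1.0 ± 0.24). Arhgef37 was at least 1.62-fold lower. LOC100196483, with the synonym atp7a of a copper transporter, rose by 1.29 ± 0.21 (adjusted p = 0.000497, above every T12 fish in 6 of 6). The other highest rises were in the neuronal splicing factor nova2 (1.54 ± 0.36), macf1b (1.41 ± 0.33, or 0.90 without F_P1 fish 6), st1s3 (1.31 ± 0.31) and fsip1 (1.21 ± 0.29). They were followed by the purinergic receptor p2rx1 (1.04 ± 0.25), phlda1 (0.85), eif4a2 (0.76), ttyh3a (0.75 ± 0.16) and atxn1a (0.73).

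Of 14 proteasome and ubiquitin genes none was called in F against T12 at P1, and 13 lay below 0 (median −0.27, camera adjusted p = 0.00694; adjusted p = 0.83 with an estimated correlation). Among them were uchl5 (−0.73), psmd1 (−0.48) and psmd2 (−0.31). Of 17 genes of scale and bone cells none was called, 1 fell when adjusted over the list alone, and 14 lay below 0 (median −0.58, camera adjusted p = 0.0153; adjusted p = 0.83 with an estimated correlation). Osteocalcin bglap stood at −2.92 ± 0.87, spp1 at −1.79 and entpd5a at −2.43. Without F_P1 fish 6 this call was lost (camera adjusted p = 0.283), and spp1 and entpd5a both stood at −0.80. Skeletal muscle genes, not called (camera adjusted p = 0.387), also lay lower, with a median of −0.98 that turned to 0.12 with the slide as a block. Of 38 ribosomal proteins 1 fell and 33 lay below 0 (median −0.10, camera adjusted p = 0.0141; adjusted p = 0.83 with an estimated correlation). Examples were rpl36a (−0.28) and rpl7a (−0.39). This call too was lost without F_P1 fish 6 (camera adjusted p = 0.721), where these genes stood at −0.18 and −0.20, and the list's median was already −0.13 before the trial. The medians of the scale and ribosomal lists were −0.21 and 0.00449 with the slide as a block. None of 13 heat shock proteins was called (median 0.03, camera adjusted p = 0.743), with hsp90ab1 at 0.09, hspa1b at 0.42 ± 0.96 (−0.11 without F_P1 fish 2), hspa8 at −0.35 (−0.18 without F_P1 fish 6) and serpinh1a at 0.31.

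Limma called 279 probes in F against T12 at P1, 72 higher and 207 lower, with 4624 at an unadjusted p under 0.05. The count was 101 without T12_P1 fish 2, 30 higher and 89 lower without T12_P1 fish 3, 138 without F_P1 fish 6, 143 without T12_P1 fish 1, and 159 without F_P1 fish 1. It was 570 without F_P1 fish 3 and 658 without T12_P1 fish 4. An unadjusted p under 0.05 with a log2 difference of 0.8 gave 765 higher and 635 lower. The count was 4 after normexp, where tmem86a (0.0629) and vars1 (0.00915) changed sign. It was 5 with tank means, 7 with the slide as a block and 1 when the fit held the compared arrays alone. LOC100196483, ttyh3a, apbp2, LOC100196055, unga, faub and cirbpb stayed under the threshold without any 1 of the 12 arrays. The other calls were lost without 1 to 9 of them, to adjusted p of 0.133 for fsip1, 0.124 for tmem86a, 0.116 for arhgef37, 0.114 for st1s3 and 0.106 for nova2, all without F_P1 fish 6. Without T12_P1 fish 2 it was 0.146 for rsl1d1 and 0.111 for npm.

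Constant and fluctuating heat were set against each other at P1. Dachd, a dachshund transcription factor, fell by 2.28 ± 0.51 in H relative to F (adjusted p = 0.0102). Drc5 of the dynein regulatory complex of cilia (−2.24), spata17 (−1.88) and the cilium gene cfap99 (−1.73 ± 0.49) followed. Also lower were lrrc4ba (−1.81), cg024 (−1.63), anxa13l (−1.62), rprma (−1.52 ± 0.37), nova2 (−1.51 ± 0.36) and zzef1 (−1.49). F_P1 fish 6, with its high cilia genes, was the highest of its group for dachd, cfap99, cg024, anxa13l and nova2, among others. Without it cfap99 stood at −0.85, anxa13l at −0.93 and cg024 at −1.06. The level of drc5 was −0.56 in this fish, against a mean of −4.20 in the other F_P1 fish. The Wnt inhibitor dkk1b rose by 2.68 ± 0.67 (adjusted p = 0.0194), and ptchd3b by 1.92 ± 0.38 (adjusted p = 0.00502). The others highest in H were frrs1a (2.60), the chitinase chia.1 (2.49), pik3ap1 (2.34), phf1 (2.06) and glt1d1 (1.95). Without signal above background in F, tyw3 was at least 1.73-fold, the prokineticin receptor prokr1a at least 1.26-fold and bco2l at least 1.27-fold higher in H.

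Of 32 cell cycle genes 27 lay above 0 in H against F at P1 (median 0.29, camera adjusted p = 0.00241; adjusted p = 0.83 with an estimated correlation). Examples were mcm7 (0.65 ± 0.23), mcm3 (0.71) and bub1 (0.57, or 0.32 without F_P1 fish 6), none called. Of 22 skeletal muscle genes 21 lay above 0 (median 1.72, camera adjusted p = 0.00904; adjusted p = 0.83 with an estimated correlation). Ldb3 stood at 0.94, smyd1b at 2.07 and ampd1 at 2.55 ± 1.35 (1.58 without H_P1 fish 3), none called. Interferon genes lay above 0 in 16 of 17 cases (median 0.39, camera adjusted p = 0.00904; adjusted p = 0.83 with an estimated correlation). Examples were dhx58 (0.63), psmb8b (0.51) and xaf1 (0.50), of which dhx58 and xaf1 stood at 0.26 and 0.19 without H_P1 fish 6. Of 34 mitochondrial genes 1 rose, cox6a1 by 0.32 ± 0.10 (adjusted p = 0.0489), and 29 lay above 0 (median 0.18, camera adjusted p = 0.00904; adjusted p = 0.863 with an estimated correlation). Examples were vdac2 (0.51) and cox5ba (0.29). Leaving out F_P1 fish 6 kept these 4 calls and added the antioxidant, glycolysis, proteasome and ribosomal lists (camera adjusted p from 0.000547 to 0.0398), the last lying lower in H. Before the trial mitochondrial and muscle genes already lay higher in H than in F, at medians of 0.59 and 0.89. Hsp90ab1 (−0.06), hspa1b (0.27), hspa8 (0.13), serpinh1a (−0.23) and cirbpb (0.22) were not called, and leaving out H_P1 fish 3 turned hspa1b to −0.33 and F_P1 fish 6 hspa8 to −0.03.

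Limma called 1662 probes in H against F at P1, 596 higher in H and 1066 lower, with 7366 at an unadjusted p under 0.05. The count was 632 without H_P1 fish 5, 762 without F_P1 fish 1, 769 without H_P1 fish 4 and 967 without H_P1 fish 3, and 1303 without F_P1 fish 6 (294 higher and 1009 lower), 876 of them shared. It was 4 after normexp, which turned tyw3, frrs1a, chia.1, prokr1a, bco2l, glt1d1, ldb3 and hspa1b to between −0.311 and −0.00702. It was 0 with tank means and 239 in a fit to the compared arrays alone. The H arrays had a scan day of their own. Tyw3, prokr1a, ptchd3b, dachd, rprma and nova2 stayed under the threshold without any 1 of the 12 arrays. The other calls were lost without 1 to 10 of them, among them drc5 (adjusted p = 0.0865), spata17 (0.112), lrrc4ba (0.116), cg024 (0.133), phf1 (0.13) and dkk1b (0.0545) without F_P1 fish 6. Those of chia.1 (0.0897) and cfap99 (0.0659) were lost without H_P1 fish 5.

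At P2, col13a1, bgnb, bmp2 and pitx1 were among the genes higher in skin from constant heat than at 12 °C, while the fixed list of dermal collagens and matrix was not called (median −0.26, 6 of 18 above 0, camera adjusted p = 0.618). The transmembrane collagen col13a1 rose by 2.17 ± 0.38 (adjusted p = 0.0013, above every T12 fish in 6 of 6), and the proteoglycan bgnb by 1.80 ± 0.44 (adjusted p = 0.0314). Both also fell from P1 to P2 in T12, and those falls and these rises share the T12_P2 arrays. The bone growth factor bmp2 rose by 1.34 ± 0.30 (adjusted p = 0.0173) and the limb transcription factor pitx1 by 1.28 ± 0.29 (adjusted p = 0.0205). Tnfrsf11b, the osteoclast inhibitor osteoprotegerin, fell by 1.46 ± 0.35 (adjusted p = 0.0268). The netrin receptor unc5cb was at least 1.22-fold higher. The immediate early genes ier2 (1.77 ± 0.43, or 1.17 without H_P2 fish 6) and ier2a (1.39), hs3st3b1b (1.61), phlda2 (1.03) and LOC100196483 (0.96 ± 0.21) made up the other highest rises. The fatty acid desaturase fadsd5 fell by 1.21 ± 0.22 (adjusted p = 0.00175), pfkfb4a, an enzyme that sets fructose 2,6-bisphosphate, by 1.24 ± 0.29 (adjusted p = 0.021), and fbxo32 by 1.47 ± 0.34 (adjusted p = 0.0235). The others were golt1a (−1.87), bat1 (−1.57), the prohormone convertase pcsk2 (−1.33), yk005 (−1.21) and gbp (−1.20), with stxb6 at least 1.62-fold lower.

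Of 17 genes of scale and bone cells 1 rose and 1 fell in H against T12 at P2, 8 rose and 1 fell when adjusted over the list alone, and 13 lay above 0 (median 0.89, camera adjusted p = 0.000196; adjusted p = 0.329 with an estimated correlation). The osteoblast factor msx2b stood at 1.5 ± 0.43 and sp7 at 2.02 ± 0.58. Of 8 glucocorticoid-responsive genes 2 fell, 5 fell when adjusted over the list alone, and 6 lay below 0 (median −0.90, camera adjusted p = 0.00133, fry adjusted p = 0.00874; adjusted p = 0.18 with an estimated correlation). Tsc22d3, a mediator of glucocorticoid action, fell by 0.86 ± 0.18 (adjusted p = 0.0109) and per1b was at least 2.00-fold lower without passing the threshold. The list's median was −0.48 without T12_P2 fish 2 and 6, and the call held (camera adjusted p = 0.0166). Of 12 clock genes ciarta fell by 0.94 ± 0.19 (adjusted p = 0.00868), 9 lay below 0 as did dbpb (−0.65), and the median was −0.20 (camera adjusted p = 0.0167, fry adjusted p = 0.0345; adjusted p = 0.329 with an estimated correlation). Interferon genes lay above 0 in 15 of 17 cases (median 0.27, camera adjusted p = 0.00133; adjusted p = 0.436 with an estimated correlation). Examples were eif2ak2 (0.36), rigi (0.37) and isg15 (1.02 ± 0.50). Antigen presentation genes lay above 0 in 6 of 7 cases (median 0.33, camera adjusted p = 0.0167; adjusted p = 0.436 with an estimated correlation). Examples were tap2b (0.44), psmb8b (0.38) and tap2a (0.66), and the call was lost without T12_P2 fish 2 and 6 (camera adjusted p = 0.155). Skeletal muscle genes lay above 0 in 18 of 22 cases (median 0.91, camera adjusted p = 0.00674; adjusted p = 0.859 with an estimated correlation). Tnnt1 stood at 3.78 ± 1.05, myoz1 at 1.88 (1.23 without H_P2 fish 3) and tnni2a.2 at least 5.27-fold higher, and the list's median was 2.17 with the slide as a block. The interferon, antigen presentation and muscle medians of H against T12 were already 0.38, 0.38 and 0.94 before the trial. Of 19 complement and coagulation genes, made mainly by liver, none was called, 6 fell when adjusted over the list alone, and 17 lay below 0 (median −1.26, camera adjusted p = 0.000196; adjusted p = 0.379 with an estimated correlation). Examples were f9a (−2.25 ± 0.79), fga (−2.51) and c8a (−1.48), at −1.26, −1.40 and −0.79 without T12_P2 fish 2. Without T12_P2 fish 2 and 6, which carried liver genes, their median was −0.14 (camera adjusted p = 0.994). None of 13 heat shock proteins was called (median 0.04, camera adjusted p = 0.29), with hsp90ab1 at 0.33, hspa1b at 1.54 ± 0.96 (0.85 without H_P2 fish 3), hspa8 at −0.21 and serpinh1a at −0.28, and cirbpb stood at −0.60 ± 0.16 (adjusted p = 0.0601).

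**Figure D2:**
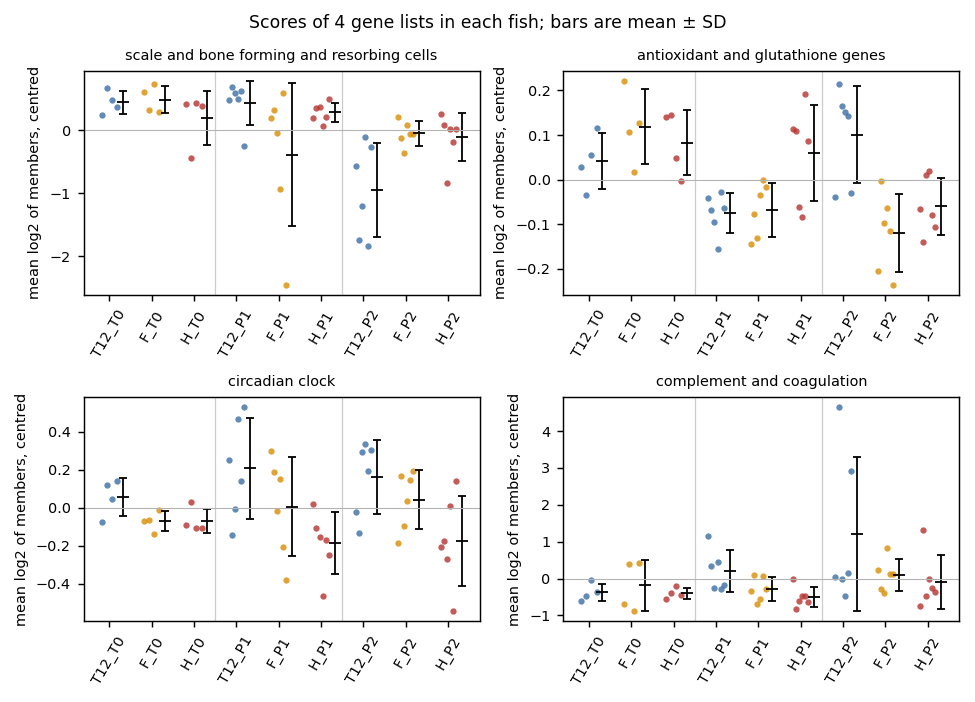
Each point is the mean log2 level of a gene list on 1 array, centred on all arrays, by regime and stage, with group means and SD, for scale and bone, antioxidant, clock, and complement genes. The scale and bone genes had a median log2 difference of −1.23 from P1 to P2 in T12, and of 0.89 and 0.63 in H and F against T12 at P2.

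Limma called 280 probes in H against T12 at P2, 155 lower and the others higher, with 3973 at an unadjusted p under 0.05, all arrays being from 1 scan day. The count was 127 without H_P2 fish 1, 140 without H_P2 fish 2, 179 without T12_P2 fish 3 and 184 without T12_P2 fish 6. Without T12_P2 fish 2 and 6 together 57 probes were higher and 67 lower, and without F_P1 fish 6 the count was 593, including all 280. It was 11 after normexp, where unc5cb (−0.29), bgnb (−0.00549), myoz1 (−0.23) and msx2b (−0.29) changed sign. It was 25 with tank means, 522 with the slide as a block (174 higher and 348 lower), and 164 with the authors' table (44 higher and 120 lower). Col13a1, unc5cb, LOC100196483, fadsd5, tsc22d3 and ciarta stayed under the threshold without any 1 of the 12 arrays. The other calls were lost without 3 to 8 of them, to adjusted p of 0.106 for bgnb without T12_P2 fish 5, 0.096 for tnfrsf11b without H_P2 fish 1 and 0.14 for phlda2 without H_P2 fish 6.

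Under fluctuating heat at P2, 166 of the 208 called probes were lower than at 12 °C, a balance that an unadjusted p under 0.05 with a log2 difference of 0.8 turned (898 higher and 352 lower). Unga fell by 1.04 ± 0.13 (adjusted p = 1.29e-05), apbp2 by 1.18 ± 0.18 (adjusted p = 0.000312) and cirbpb by 0.90 ± 0.16 (adjusted p = 0.00209). Ciarta fell by 1.04 ± 0.19 (adjusted p = 0.00318) and pfkfb4a by 1.67 ± 0.29 (adjusted p = 0.00106). In each of these all 6 F fish lay below every T12 fish. Among the other falls were the fatty acid desaturase scdb (−1.32 ± 0.28, adjusted p = 0.0106), the exonuclease exo1 (−1.10 ± 0.24, adjusted p = 0.0168) and the DNA polymerase subunit pole (−0.65 ± 0.16, adjusted p = 0.041). Tp53i11b (−1.74), etnppl (−1.62), npm (−1.41 ± 0.34) and yk005 (−1.24) were the other lowest. Only 8 named genes rose: col13a1 by 1.59 ± 0.38 (adjusted p = 0.033), the neural phosphatase receptor ptprz1a by 1.31 ± 0.29, and vstm4b by 0.90. The rest were the kynurenine pathway enzyme afmid (0.79 ± 0.16), zgc:112271 with the synonym bola2 (0.76), f264 (0.72 ± 0.14), the lysine methyltransferase setd7 (0.62 ± 0.11, adjusted p = 0.00154) and the deubiquitinase usp25 (0.49).

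**Figure D3:**
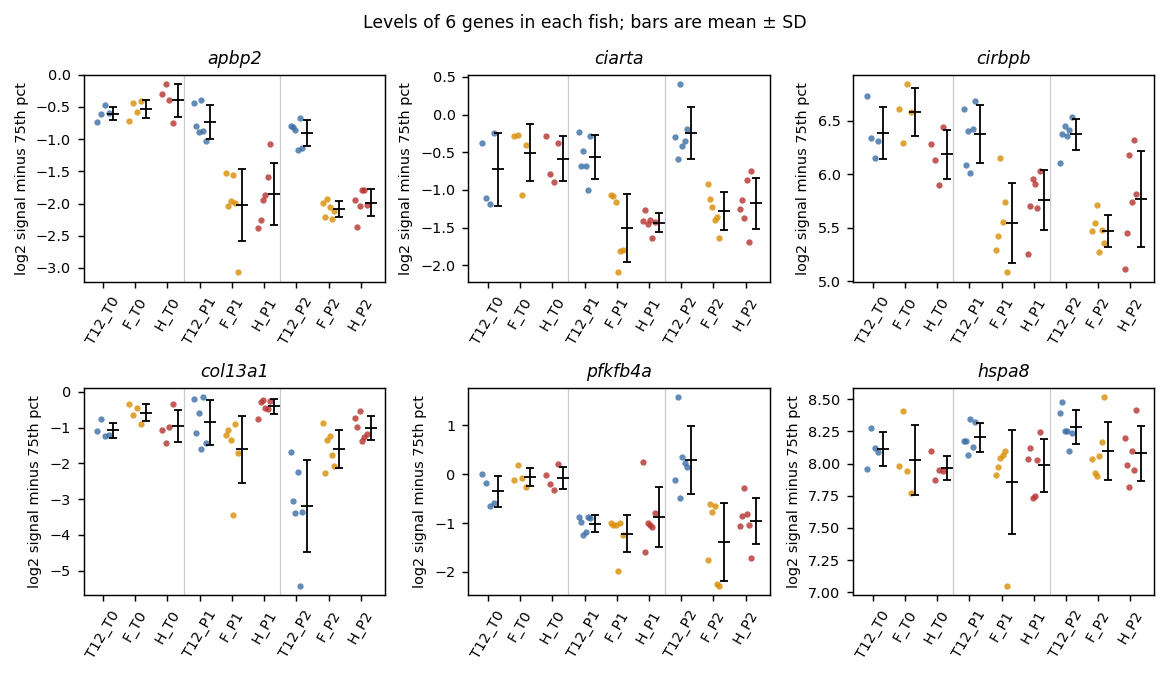
Each point is the log2 level of a gene on 1 array relative to the array's 75th percentile, by regime and stage, with group means and SD, for apbp2, ciarta, cirbpb, col13a1, pfkfb4a and hspa8. Apbp2 lay lower in both warm regimes than in T12, by 1.12 and 1.29 on the log2 scale at P1 and by 1.08 and 1.18 at P2, while hspa8 stood at −0.22, −0.35, −0.21 and −0.18 in the same comparisons.

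Of 27 antioxidant and glutathione genes none was called in F against T12 at P2 and 22 lay below 0 (median −0.23, camera adjusted p = 0.000434, and adjusted p = 0.0244 with an estimated correlation). Examples were gpx1a (−0.33), gclc (−0.53) and gsr (−0.45). Of 32 cell cycle genes 1 fell, 12 fell when adjusted over the list alone, and 24 lay below 0 (median −0.23, camera adjusted p = 6.54e-06; adjusted p = 0.302 with an estimated correlation). Examples were rfc2 (−0.80) and cdk2 (−0.66). Mitochondrial genes lay below 0 in 31 of 34 cases (median −0.19, camera adjusted p = 0.000188; adjusted p = 0.489 with an estimated correlation). Examples were cox6a1 (−0.26), cox8a (−0.36) and cox5ba (−0.28). With the slide as a block the list's median was 0.00869 and its mean 0.04, so its direction was not kept in that fit, where F and T12 shared only slides 3 and 11. Proteasome genes lay below 0 in 13 of 14 cases (median −0.35, camera adjusted p = 0.000188; adjusted p = 0.219 with an estimated correlation). Examples were psmd2 (−0.33), ubb (−0.44) and uchl5 (−0.56). All 11 sterol synthesis genes lay below 0 (median −0.39, camera adjusted p = 0.0013; adjusted p = 0.219 with an estimated correlation). Examples were acat2 (−0.86), insig1 (−0.55) and mvk (−0.26). Of 21 adipocyte genes scdb alone fell and 14 lay below 0 (median −0.11, camera adjusted p = 0.00859; adjusted p = 0.249 with an estimated correlation). Elovl6 stood at −0.81 and cidec at −1.60. Of 10 hypoxia-responsive genes 9 lay below 0 (median −0.29, camera adjusted p = 0.00691, fry adjusted p = 0.0286; adjusted p = 0.147 with an estimated correlation). Examples were p4ha1 (−0.61), vegfab (−1.15) and ndrg1a (−0.41). Of 19 glycolysis genes pfkfb4a fell and 10 lay below 0. Camera ranked the list lower with a median of −0.06 but a mean of 0.06 (camera adjusted p = 0.0298; adjusted p = 0.159 with an estimated correlation). Tpi1a stood at −0.57 and gpia at −0.35. With the slide as a block the medians of the cell cycle, adipocyte, hypoxia and glycolysis lists were −0.39, −0.34, −0.19 and −0.16.

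In the same comparison of F with T12 at P2, 15 of 17 scale and bone genes lay above 0, none called and 6 risen when adjusted over the list alone (median 0.63, camera adjusted p = 0.000188, fry adjusted p = 0.0483; adjusted p = 0.219 with an estimated correlation). Msx2b stood at 1.57 ± 0.43, bmp2 at 1.08 and sp7 at 1.77 ± 0.58. Skeletal muscle genes lay above 0 in 16 of 22 cases beside them (median 1.07, or 2.16 with the slide as a block), without a call (camera adjusted p = 0.0707) unless T12_P2 fish 2 and 6 were left out (camera adjusted p = 0.0453; adjusted p = 0.924 with an estimated correlation). All 7 antigen presentation genes lay above 0 (median 0.31, camera adjusted p = 0.0263; adjusted p = 0.371 with an estimated correlation). Examples were tap2b (0.55), tapbp (0.37) and tap2a (0.59), and the list's median was already 0.71 before the trial. Of 8 glucocorticoid-responsive genes tsc22d3 fell by 0.91 ± 0.18 (adjusted p = 0.00656) and 6 lay below 0 (median −0.36, camera adjusted p = 0.0267; adjusted p = 0.219 with an estimated correlation). Tat stood at −2.06 (−1.0 without T12_P2 fish 2) and mt2 at −0.30. Of 12 clock genes ciarta fell and 10 lay below 0 (median −0.17, camera adjusted p = 0.0402; adjusted p = 0.219 with an estimated correlation). Examples were bhlhe40 (−0.38) and dbpb (−0.48), and with the slide as a block the list's median was −0.24 and its mean 0.01. Of 13 chaperones of the endoplasmic reticulum 9 lay below 0 (median −0.15, camera adjusted p = 0.033; adjusted p = 0.302 with an estimated correlation). Examples were edem1 (−0.39), dnajc3a (−0.60) and manf (−0.71). Complement and coagulation genes lay below 0 in 16 of 19 cases (median −1.02, camera adjusted p = 0.000198; adjusted p = 0.219 with an estimated correlation). F10 stood at −1.27 (−0.72 without T12_P2 fish 2), f9a at least 1.11-fold and f7 at least 1.09-fold lower. Without T12_P2 fish 2 and 6 their median was 0.09 (camera adjusted p = 0.77). Without these 2 fish the calls of the glycolysis and glucocorticoid (camera adjusted p = 0.132 for each), antigen presentation (0.201), adipocyte (0.249) and endoplasmic reticulum lists (0.0955) were also lost. The medians of the scale and glucocorticoid lists were 1.02 and −0.66 with the slide as a block. None of 13 heat shock proteins was called. Their median was 0.06 and mean 0.16 where camera ranked them lower (adjusted p = 0.909), with hsp90ab1 at 0.29, hspa1b at 1.27 (0.66 without F_P2 fish 3), hspa8 at −0.18 and serpinh1a at −0.06.

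Limma called 208 probes in F against T12 at P2, 42 higher and 166 lower, with 4101 at an unadjusted p under 0.05. The count was 99 without T12_P2 fish 5, 100 without T12_P2 fish 3, 108 without F_P2 fish 5, 73 without T12_P2 fish 2 and 6 together, and 433, including all 208, without F_P1 fish 6. Higher and lower probes numbered 27 and 82 without F_P2 fish 6, 23 and 93 without T12_P2 fish 2, 29 and 92 without F_P2 fish 1 and 27 and 97 without F_P2 fish 4. The count was 11 after normexp, where msx2b (−0.23) and serpinh1a (0.0913) changed sign. It was 10 with tank means and 41 with the slide as a block. Afmid, f264, setd7, pfkfb4a, scdb, apbp2, unga, ciarta, tsc22d3 and cirbpb stayed under the threshold without any 1 of the 12 arrays. The other calls were lost without 1 to 10 of them, to adjusted p of 0.129 for col13a1 without T12_P2 fish 5, and 0.162 for etnppl without T12_P2 fish 2. It reached 0.139 for npm without F_P2 fish 1 and 0.114 for pole without T12_P2 fish 3.

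Between constant and fluctuating heat at P2 limma called 0 probes, with 2141 at an unadjusted p under 0.05 against 1693 by chance. In simulation 16 of 50 probes changed by 1 were recovered in this comparison, so 0 calls do not show that the regimes were alike. The authors' table gave 0 calls and array weights 48. All 9 lists called by camera lay higher in H. Mitochondrial genes did so in 31 of 34 cases (median 0.30, camera adjusted p = 2.89e-11; adjusted p = 0.279 with an estimated correlation). Examples were cox4i1 (0.30 ± 0.11), ndufs6 (0.38) and atp5g3 (0.63), the last pair at 0.24 and 0.38 without H_P2 fish 4, and the list's median was already 0.59 before the trial. Cell cycle genes lay above 0 in 25 of 32 cases (median 0.23, camera adjusted p = 1.87e-05; adjusted p = 0.487 with an estimated correlation). Examples were mcm4 (0.44 ± 0.19), lig1 (0.32) and pole (0.36). Proteasome genes lay above 0 in 12 of 14 cases (median 0.22, camera adjusted p = 8.33e-05; adjusted p = 0.195 with an estimated correlation). Examples were uchl5 (0.60), psme3 (0.46) and psmd2 (0.27). Sterol genes lay above 0 in 8 of 11 cases (median 0.38, camera adjusted p = 0.0201; adjusted p = 0.359 with an estimated correlation). Examples were lss (0.89), hmgcs1 (0.67) and stard4 (0.55). The antibacterial (median 0.41, 7 of 8 above 0), antioxidant (0.11, 15 of 27), glycolysis (0.16, 12 of 19) and hypoxia lists (0.24, 7 of 10) each had a camera adjusted p = 0.0478, and adjusted p = 0.173 with an estimated correlation. Their members with the smallest p included fth1b (0.83), saa5 (1.35), mt (0.73), srxn1 (0.32), gsta3 (0.41), slc16a3b (1.05), hk2 (0.34), pfkfb4a (0.43), higd1a (0.52), egln2 (0.35) and ca9 (1.26). The iron hormone hamp was at least 1.44-fold higher. With the slide as a block the medians of the antibacterial, antioxidant, glycolysis and hypoxia lists were 1.04, 0.06, 0.24 and 0.0999. Interferon genes lay above 0 in 12 of 17 cases (median 0.12, camera adjusted p = 0.0478; adjusted p = 0.766 with an estimated correlation). Examples were pkz (0.40), cmpk2 (0.48) and stat2 (0.22). Hsp90ab1 (0.05), hspa1b (0.26), hspa8 (−0.02), serpinh1a (−0.21) and cirbpb (0.30) were not called, and hspa1b turned to −0.42 without H_P2 fish 3. Signs changed for hsp90ab1 (−0.00726) after quantile normalisation and for hspa8 (0.0212) after normexp.

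Some probes were called in both warm regimes and at both stages. There were 26 of them, 7 higher and 19 lower, each with the same direction in all 4 comparisons with T12. Of these 5 had a symbol, namely apbp2, ciarta, unga, the signal peptidase subunit spcs2 and galcb, which breaks down galactosylceramide. Spcs2 fell by 0.73 and 0.95 at P1 and by 0.72 and 0.82 at P2 in H and F, and galcb by 0.46, 0.54, 0.47 and 0.52. At P1, 19 probes rose and 60 fell in both regimes, and at P2 24 and 49. There was no probe called in opposite directions. These comparisons share their T12 fish, and the overlap of calls that shared fish alone would give was not computed. Across probes, which are not independent replicates, the H and F differences correlated at r = 0.307 at P1 and 0.742 at P2, where shared T12 fish alone gave a mean r of 0.486 (0.0257 to 0.891 over 100 draws) and 0.503 (−0.0757 to 0.868) in simulation, so both observed values lay within the simulated range. The covariance was 0.0741 at P1 and 0.192 at P2, against a simulated mean of 0.1005 and 0.0911. With separate T12 fish for each regime r was 0.00343 at P1 and 0.342 at P2.

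Constant 12 °C fish changed from P1 to P2 in the genes of scale and bone. Col13a1 fell by 2.34 ± 0.38 (adjusted p = 0.00361), bgnb by 2.44 ± 0.44 (adjusted p = 0.00874), hs3st3b1b by 1.86 ± 0.39 (adjusted p = 0.0252) and the enamel protease mmp20b by 2.22 (adjusted p = 0.0491), and unc5cb was at least 1.40-fold lower. The germline helicase ddx4 rose by 2.26 ± 0.54 (adjusted p = 0.0494), mfap4 by 2.10, lrfn4a by 1.60, the growth factor vegfd by 1.30 and pfkfb4a by 1.29 ± 0.29. Of 17 scale and bone genes 1 fell, 9 fell when adjusted over the list alone, and all 17 lay below 0 (median −1.23, camera adjusted p = 4.73e-09, fry adjusted p = 0.0028, and adjusted p = 0.05 with an estimated correlation, which lay just under the threshold before rounding). Of 21 adipocyte genes 6 rose when adjusted over the list alone (median 0.23, mean 0.88, camera adjusted p = 1.28e-06, and adjusted p = 0.05 with an estimated correlation). Without T12_P2 fish 2 and 6 the latter was 0.181 for the adipocyte list and 0.0424 for the scale and bone list. Skeletal muscle (median 1.20, camera adjusted p = 0.000705; adjusted p = 0.576 with an estimated correlation) and complement genes (1.29, camera adjusted p = 5.71e-05; adjusted p = 0.24 with an estimated correlation) lay higher at P2. So did the cell cycle (median 0.17), antioxidant (0.09), mitochondrial (0.19) and glycolysis lists (0.18), with camera adjusted p from 8.26e-07 to 0.0479 and none called with an estimated correlation. Without T12_P2 fish 2 and 6 the complement median turned to −0.27 (camera adjusted p = 0.666) and the glycolysis call was lost (camera adjusted p = 0.184). The scale list here and in H and F against T12 at P2 rests on the same 6 T12_P2 arrays, and fish 2, 3 and 5 of these had low scores (−1.74, −1.21 and −1.83). The falls of col13a1, bgnb, hs3st3b1b and unc5cb here and their rises in H at P2 share these arrays. The rise of pfkfb4a and its falls in H and F at P2 do so too. With the slide as a block, which links the stages only through F_P1 fish 6, the medians of the scale and antioxidant lists turned to 1.41 and −0.23.

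Limma called 101 probes in T12 from P1 to P2, 37 higher and 64 lower, across 2 scan days. The count was 7 without T12_P2 fish 2, 8 without T12_P1 fish 3, 23 without T12_P1 fish 5, 28 without T12_P1 fish 2, 29 without T12_P1 fish 1, 46 without T12_P2 fish 5 and 60 without T12_P2 fish 3. It was 222 without F_P1 fish 6, 20 without T12_P2 fish 2 and 6 together, 4 with tank means, 1 after normexp, which turned ddx4 to −0.0099, and 50 with the authors' table (12 higher and 38 lower). A fit to the compared arrays alone turned the balance, with 70 higher and 12 lower, 20 of them shared. Bgnb, col13a1 and unc5cb stayed under the threshold without any 1 of the 12 arrays. The other named calls were lost without 5 to 10 of them, to adjusted p of 0.243 for mmp20b and 0.179 for pfkfb4a without T12_P2 fish 2. From T0 to P1 in T12, limma called 1 probe, LOC106603096, which fell by 2.82 ± 0.50 (adjusted p = 0.0444). The count was 0 without T12_T0 fish 3 or 4 or T12_P1 fish 3 or 5, and between 3 and 7 without T12_T0 fish 1 or 2, T12_P1 fish 1 or 2 or F_P1 fish 6. In the same comparison all 34 mitochondrial genes lay below 0 (median −0.22, camera adjusted p = 4.16e-06; adjusted p = 0.875 with an estimated correlation).

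Whether the warm regimes changed differently from T12 between P1 and P2 was tested directly. In H, LOC106608146 changed by −2.37 ± 0.41 relative to T12 (adjusted p = 0.0273), and in F LOC106561179 by 1.88 ± 0.32 (adjusted p = 0.0144). The change of unc5cb was at least 2.27-fold higher in H than in T12 (adjusted p = 0.0436), a bound, since no T12_P2 array had it above background. These were the only probes called, 2 and 1, and the LOC genes were named after their values were seen. Both counts were 0 after quantile normalisation, after normexp, with the authors' table and with tank means, and the F count also with the slide as a block. The unc5cb call was lost without any 1 of 16 of the 24 arrays, to adjusted p of 0.161 without T12_P2 fish 5, and the H count was 0 without H_P1 fish 1, H_P1 fish 5, H_P2 fish 4, T12_P1 fish 3, T12_P1 fish 4, T12_P2 fish 1 or T12_P2 fish 5 and 1 without H_P1 fish 3, 4 or 6, H_P2 fish 1, 2 or 6, T12_P1 fish 5 or T12_P2 fish 3. The F count was 0 without T12_P1 fish 2 or 3, F_P1 fish 1 or 4, T12_P2 fish 5 or F_P2 fish 3, and 2 without T12_P1 fish 4 or 6 or F_P1 fish 5. A larger count at 1 stage than at the other does not show that the effect of heat differed between the stages.

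Before the trial, with all tanks at 1 temperature, limma called 0 probes in each comparison, with 1561, 1988 and 2019 at an unadjusted p under 0.05 for H against T12, F against T12 and H against F. The authors' table gave 0 calls, and array weights 632, 3068 and 23. Camera called 8, 5 and 4 lists there, against 4, 3 and 4 at P1 and 7, 14 and 9 at P2, and none of those at T0 with an estimated correlation. Without F_P1 fish 6 the lists numbered 8, 7 and 5 at T0, 5, 1 and 8 at P1 and 7, 14 and 10 at P2. Below, each list's median is followed by its camera adjusted p and, where given, the adjusted p with an estimated correlation. In H against T12, mitochondrial genes (0.69, 1.29e-22; 0.304), interferon genes (0.38, 4.82e-07; 0.356), antigen presentation (0.38, 2.96e-05; 0.33), skeletal muscle (0.94, 0.0141) and inflammatory mediators (0.22, 0.0117) lay higher. Lower were dermal collagens (−0.46, 0.000742; 0.483), ribosomal proteins (−0.20, 1.69e-07; 0.712) and metalloproteinases (−0.34, 0.049). In F against T12, cell cycle genes (0.40, 1.94e-13; 0.176), interferon genes (0.61, 3.97e-11; 0.12), antigen presentation (0.71, 1.62e-07; 0.12) and proteasome genes (0.23, 0.000344) lay higher and ribosomal proteins lower (−0.13, 0.0251). Cell cycle (−0.62, 9.59e-20; 0.177) and proteasome genes (−0.33, 3.36e-05; 0.474) lay lower in H than in F, mitochondrial (0.59, 1.28e-12; 0.541) and muscle genes (0.89, 0.0496) higher. With the slide as a block the medians in F against T12 were 0.18 for cell cycle, 0.32 for antigen presentation, 0.06 for proteasome (mean −0.03) and −0.04 for ribosomal genes, and that of proteasome genes in H against F was −0.13. With the T0 difference subtracted, H against T12 had 3 calls at P1 and 2 at P2, F against T12 had 56 and 29, and H against F had 2 at P1.

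Lists with no camera call in any of the 6 comparisons of regimes at P1 and P2 are given by the range of their medians there and their lowest camera adjusted p. Heat shock proteins ranged from 0.03 to 0.11 (0.0803), dermal collagens and matrix from −0.26 to 0.20 (0.387), metalloproteinases from −0.24 to 0.16 (0.24), keratins and epidermal adhesion from −0.14 to 0.26 (0.398) and mucus products, with 5 members, from −0.55 to 0.29 (0.269). Inflammatory mediators ranged from −0.13 to 0.30 (0.0851), B cell genes from −0.20 to 0.33 (0.168), T cell genes from −0.35 to 0.18 (0.0783), neutrophil and macrophage genes from −0.06 to 0.22 (0.159) and erythrocyte genes from −0.92 to 0.27 (0.261). Pigment cell genes ranged from −0.23 to 0.12 (0.371), ion transport from −0.12 to 0.11 (0.723) and xenobiotic metabolism from −0.19 to 0.37 (0.162). In the collagen list for H against T12 at P1 the median was −0.08 and the mean 0.06. The cold-inducible list had cirbpb as its 1 measured member.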

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

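The tests of tissue, of signal strength, of the scan day at P1 and of the dermal share were chosen only after the results they bear on were seen, as was leaving out F_P1 fish 6 or T12_P2 fish 2 and 6. A fish is named below when its gap to the nearest fish of its group, divided by the group's range, passed Dixon's 95% limit. This held in 49 of 534 groups tested, where chance alone gives about 1 in 20.

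F_P1 fish 6 stood apart from the other arrays, with a median correlation of 0.854 against 0.943 for the next of its group (gap over range 0.852). Its signal was not weak, since 73.5% of its spots were well above background, within the range of the other arrays, and it did not follow its scan day, since at its divergent probes the F_P2 arrays of that day differed from the other F_P1 arrays by a median share of only 0.0205 of its difference. A candidate explanation is that the sample held tissue of another body region: its motile cilia genes lay at a median of 3.63 where the other arrays lay between −1.08 and 0.64, its 3 olfactory neuron genes at 4.82 (others −1.66 to 1.04) and its trunk hox genes at −3.59 (others −0.56 to 1.35). Ciliated cells and olfactory neurons occur in the nasal epithelium, and trunk hox genes mark the body behind the head, but the sampling site is not in the labels and a mislabelled sample was not tested. Its highest genes included cfap99 (gap over range 0.831), anxa13l (0.731), st1s3 (0.724), cg024 (0.655), nova2 (0.646), macf1b (0.639), dachd (0.629) and fsip1 (0.626), and its lowest hspa8 (0.827), rpl7a (0.687), ptchd3b (0.68), bub1 (0.674), apbp2 (0.671), the ribosomal list (0.646) and entpd5a (0.633).

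The calls of H at P1 rest on 6 arrays that were alone in their scan day. If the day were the whole cause, these probes would have no common direction at P2, where all regimes share a day, yet 75.5% of the 433 probes of H against T12 kept their direction there, against a median of 50.2% and a highest value of 82.9% in 100 permuted groupings of the P2 fish. For H against F 67.1% of 1662 kept it, against a median of 49.9% and a highest value of 86.2%. Neither share lay above 95 of the 100 groupings, so scan day and regime cannot be told apart at P1; constant heat and tank remain open beside the day. The few genes called in all 4 comparisons with T12, apbp2, ciarta, unga, spcs2 and galcb, include a comparison within 1 day and are the part least open to it.

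Scale and bone genes were higher in both warm regimes than in T12 at P2, calls that did not pass with an estimated correlation (adjusted p = 0.329 in H and 0.219 in F), while from P1 to P2 in T12 they lay lower, a call that did (adjusted p = 0.05). All of these rest on the same 6 T12_P2 arrays, where fish 2, 3 and 5 had low scores (−1.74, −1.21 and −1.83), while H_P2 lay between −0.83 and 0.26 and F_P2 between −0.35 and 0.22, each F_P2 fish below the lowest F fish before the trial (0.29), so they are largely 1 observation of low T12_P2 fish. No single array decided the difference at P2, since the mean log2 difference stayed at 0.67 or above in both regimes whichever array was left out, and with the slide as a block it was at least 0.795. More dermis in the warm samples could raise these genes, but the dermal list did not move with them, at ratios to the scale list's median of −0.29 in H and −0.0921 in F. Skeletal muscle genes did move with them at P2 (medians 0.91 in H and 1.07 in F, 2.17 and 2.16 with the slide as a block). From P1 to P2 in T12, however, muscle lay higher (1.20) where scale genes lay lower (−1.23). With the slide as a block both lay higher there (2.60 and 1.41). That block links the stages only through F_P1 fish 6, whose own scale and bone score was −2.45, so it cannot decide the direction. How deep the skin was taken, which was not tested, stays open beside scale-forming cells and the number of scales taken. The fall in T12 from P1 to P2 also crosses scan days, so the day stays open for it too.

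Other fish stood apart in single values, each given as its gap over range. Low median correlations were seen in T12_P1 fish 4 (0.799) and F_P2 fish 3 (0.694), and few spots above background in F_T0 fish 2 (0.937, 47.5% against 71.1% for the next) and F_P1 fish 5 (0.638). List scores stood out for cell cycle in H_P1 fish 1 (low, 0.848), scale and bone in T12_P1 fish 6 (low, 0.778), glycolysis in F_P2 fish 3 (high, 0.767), interferon in F_P2 fish 2 (high, 0.663), mitochondria in T12_P1 fish 5 (high, 0.662) and complement in H_P2 fish 2 (high, 0.645). H_P2 fish 6 was highest for tsc22d3 (0.665), phlda2 (0.663), ier2a (0.648) and ier2 (0.627), and lowest for saa5 (0.716). H_P2 fish 5 was highest for uchl5 (0.821), H_P2 fish 2 for f9a (0.664), and H_P2 fish 3 lowest for sp7 (0.736). H_P1 fish 1 was lowest for mcm7 (0.795) and H_P1 fish 3 for rpl17 (0.768), mast3b (0.663) and phf1 (0.642). T12_P2 fish 2, with its liver genes, was highest for etnppl (0.738) and scdb (0.687), T12_P2 fish 6 lowest for tp53i11b (0.809) and T12_P2 fish 4 lowest for rigi (0.725). T12_P1 fish 6 was highest for helt (0.641). Among F fish, fth1b was high in F_P2 fish 3 (0.8004), gpx1a low in F_P2 fish 1 (0.772), bglap low in F_P1 fish 4 (0.758), serpinh1a low in F_P1 fish 2 (0.734), and in F_P1 fish 3 eif4a2 was low (0.723) and glpk3 high (0.679).

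A direct test of the change from P1 to P2 called 3 probes, all across scan days. In H against T12 they were unc5cb by at least 2.27-fold (adjusted p = 0.0436, a bound since it was not above background in T12_P2) and LOC106608146 by −2.37 ± 0.41 (adjusted p = 0.0273). In F against T12 it was LOC106561179 by 1.88 ± 0.32 (adjusted p = 0.0144). Both counts were 0 after quantile normalisation, after normexp, with the authors' table and with tank means. For the F count chance was not excluded, since 8 of 100 splits of the fish reached it.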

How the results depend on the processing

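Of the alternatives below, normexp followed by quantile normalisation, tank means, the scan day as a block, F_P1 fish 6 left out and T12_P2 fish 2 and 6 left out were chosen only after the data were seen. Counts are calls at an adjusted p under 0.05, in the order H against T12, F against T12 and H against F at P1, then H against T12 and F against T12 at P2, unless named. With the tank as a random block all 13 counts stayed within 1.5 times the reported ones, and the fish number as a block (a paired fit) did so for 11 of 13. The estimated correlation of arrays of a tank was −0.0172, so in comparisons of regimes the tank block did not widen the errors. It therefore does not show that the counts hold against tank effects, and tank means gave far fewer calls, given below. Fish of 1 number deviated together, at a correlation over 0.1, in 5 of 6 pairs of H and T12 at P2 (mean r 0.173, 4 closest to their own number) and 3 of 6 pairs of H and F at P2 (up to 0.644), and in no comparison in all pairs. Quantile normalisation kept 262 of the single genes and lists as reported and ended 31 calls, and normexp ended 103. Normexp moved the median of all probes to −0.16 for H against T12 at P1, 0.07 for F against T12 and −0.22 for H against F, and to −0.24 and −0.18 at P2. Of the sign changes given below, some lay between 0 and this median, while those of prokr1a, bco2l, ldb3, hspa1b and narrowly tyw3 in H against F at P1, of unc5cb and msx2b in H against T12 at P2 and of msx2b in F against T12 at P2 lay beyond it. The cause of these and the other changes was not tested, apart from fewer arrays or probes where the setting itself removes them. The spot mean planned for normexp is absent from the files, so the spot median was used.

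With normexp the counts were 4, 4, 4, 11 and 11, with 0 and 0 for the changes from P1 to P2 against T12 and 1 for T12 from P1 to P2, and the correlation of the H and F differences was 0.134 at P1 and 0.849 at P2. Values that changed sign were frrs1a −0.0264, tyw3 −0.10 and hspa1b −0.14 in H against T12 at P1, tmem86a 0.0629 and vars1 0.00915 in F against T12 at P1, and in H against F at P1 tyw3 −0.22, frrs1a −0.10, chia.1 −0.00702, prokr1a −0.24, bco2l −0.26, glt1d1 −0.0889, ldb3 −0.29 and hspa1b −0.31. At P2 they were unc5cb −0.29, bgnb −0.00549, myoz1 −0.23 and msx2b −0.29 in H against T12, msx2b −0.23 and serpinh1a 0.0913 in F against T12 and hspa8 0.0212 in H against F. The change of unc5cb in H against T12 was −0.0014 and that of ddx4 in T12 −0.0099. With quantile normalisation hsp90ab1 was −0.00726 in H against F at P2, the first count was 985, the changes against T12 gave 0 and 0, and T0 to P1 in T12 gave 6. Normexp followed by quantile normalisation gave 1220, 272, 2277, 296 and 180, 19 and 0 for the changes against T12 and 11 for T0 to P1, so the low counts of normexp were not seen once quantile normalisation followed it.

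The authors' table gave 200, 78, 1076, 164 and 75, 0 and 0 for the changes against T12, and 50 for T12 from P1 to P2. Array weights gave 1905, 1015, 3111, 3796 and 649, 48 for H against F at P2, 632, 3068 and 23 at T0, 346 and 3 for the changes, 1423 for T0 to P1 and 541 for P1 to P2 in T12. Counts of 632 and 3068 before any treatment show that this setting calls probes where no regime yet existed. The compared arrays alone gave 155, 1, 239, 108 and 316, 4 and 1 for H and F against T12 at T0, 0 for the change in F and 148 for T0 to P1. An unadjusted p under 0.05 with a log2 difference of 0.8 gave 1999, 1400, 3091, 1476 and 1250, 465 for H against F at P2, 754, 848 and 768 at T0, 1558 and 1518 for the changes, 1105 for T0 to P1 and 1508 for P1 to P2, with no control of false calls. For H against T12 at P1 and P2 these were 1157 and 827 higher and 842 and 649 lower. An adjusted p with a log2 difference of 1 gave 199, 61, 705, 110 and 57. Subtracting the T0 difference gave 3, 56, 2, 2 and 29.

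Tank means, 18 units in all, gave 1, 5, 0, 25 and 10, 1 for F against T12 at T0, 0 and 0 for the changes and 4 for P1 to P2 in T12. The slide as a fixed block gave 7 for F against T12 at P1, 522 and 41 at P2, 0 for the change in F and 0 for T0 to P1. The scan day as a fixed block gave 138 for F against T12 at P1, where it takes F_P1 fish 6 out of the comparison. For P1 to P2 in T12 these blocks gave 5731 and 7279, estimable only through F_P1 fish 6, the 1 array that links the days. Probes above background on all arrays gave 950 for H against F at P1, 322 for F against T12 at P2, 0 for the change in H and 3 for T0 to P1. Without a filter the change in H gave 1, T0 to P1 gave 0 and the correlation at P2 was 0.655. The fish number as a block gave 1 for the change in H and 2 for T0 to P1. With separate T12 fish for H and F the correlations were 0.00343 and 0.342. Without T12_P2 fish 2 and 6 the P2 counts were 1.2e+02 (57 higher and 67 lower, 113 of them shared) and 73 (69 shared), and T12 from P1 to P2 gave 20 (19 shared).

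Leaving out 1 array gave 186 to 841 for H against T12, 101 to 658 for F against T12 and 632 to 2356 for H against F at P1, 127 to 593 and 99 to 433 for H and F against T12 at P2 and 0 to 0 for H against F. The 3 comparisons at T0 gave 0 to 0, 0 to 1 and 0 to 4, the changes in H and F 0 to 3 and 0 to 2, T0 to P1 0 to 7 and P1 to P2 in T12 7 to 222. Most arrays behind these shifts are named in the report beside their counts. The 2356 calls came without F_P1 fish 5, and the 3 for the change in H without T12_P2 fish 2. The calls at T0 came without T12_T0 fish 1 and without H_T0 fish 4. Camera called 67 of 341 list tests, against 3 with an estimated correlation, 10 with fry, 51 after quantile normalisation, 74 with tank means, 68 with all probes of a list and 75 without F_P1 fish 6.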

Other observations

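The test of recurrence between stages, the lists without 1 or more fish and the class of nucleolar genes were chosen only after the data were seen; the deciding value of the nucleolar test had not been seen when its bound was set. Genes of nucleolar ribosome assembly were not among the fixed lists and were examined because npm and other nucleolar genes fell in fluctuating heat. Of 80 such genes 14 fell in F against T12 at P1 and 6 at P2, npm among them, and 75 and 74 lay below 0, with medians of −0.42 and −0.34. In H against T12 the medians were −0.15 and −0.03, with 1 fallen at P1 and 0 at P2 by limma. The score of the class was −0.29 ± 0.03 (SD, n = 6) in F_P2, 0.07 ± 0.11 in T12_P2 and 0.05 ± 0.20 in H_P2, and 0.20 ± 0.26 (n = 4) in F fish before the trial.

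A hypothesis from the called genes is that fluctuating heat lowers nucleolar ribosome assembly as a class. With the 16 genes called in F left out, 58 of the other 64 lay below 0 in F against T12 at P2 (median −0.33, camera p = 0.0456 with an estimated correlation, 0.0956 after quantile normalisation and 0.0462 without F_P1 fish 6). At P1 59 of 64 lay below 0 (camera p = 0.0348 with an estimated correlation). With camera and an estimated correlation H lay above F at P2 in 60 of 64 genes (median 0.32, p = 0.00507, and p = 0.0155 after quantile normalisation), while at P1 the same test did not pass (p = 0.137, adjusted 0.206). For H against T12 camera with an estimated correlation gave p = 0.704 at P1 and 0.699 at P2. Adjusted over these 6 comparisons, the p for F against T12 was 0.0912 at both stages and that for H against F at P2 0.0304, and the tests were also run with all members and with camera's preset correlation and fry. The direct contrast of H and F at P2 passed the adjustment and those of F with T12 missed it. The 64 genes were measured on the same fish that led to the class, so they are no independent support. The adjustment does not cover the choice of the class. That the class is lower in F remains a hypothesis. Only 2 tanks held F fish, so regime and tank stay open.

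Over all probes and without F_P1 fish 6, the differences of H from T12 at P1 and P2 correlated at r = 0.307 across genes, which are not independent replicates, with a one-sided permutation p of 0.109 and a highest permuted r of 0.514. A recurring effect of constant heat over the whole transcriptome could not be told from chance. The same r was 0.123 for F against T12 and 0.246 for H against F, one-sided permutation p = 0.178 and 0.168. The F difference at P1 and that before the trial correlated at r = −0.29, below all of 100 permuted values (lowest −0.26), with a two-sided permutation p of 0.0297 and an adjusted p of 0.267 over 9 such relations. Of the 279 probes called in F against T12 at P1, 20.4% had the same sign before the trial.

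For the counts of calls, 100 splits of the same fish into groups of the same size were compared, the real one included. In H against T12 at P1 (433 calls, highest other 35) and F against T12 at P2 (208, highest other 26) no other split drawn reached the real count. The same held for H against F at P1 (1662, highest other 856) and T12 from P1 to P2 (101, highest other 53). For F against T12 at P1 (279) 2 of 100 splits reached the count, the real one included. The split that swapped T12_P1 fish 4 with F_P1 fish 6 called 535. For H against T12 at P2 (280) 3 of 100 did, the real one included, up to 1046 for that which set T12_P2 fish 3 and 5 with H fish. Why some splits called more than the real groups was not tested. For H against F at P2 another split called 1647. With 0 calls by limma for the real groups there, every split reached the real count, so the splits did not test it. For the change in H against T12 3 of 100 splits, the real one included, reached the 2 calls, and the highest other called 269. For that in F against T12 (1 call, highest other 216) chance was not excluded, as 8 splits reached it. Chance was not excluded for T0 to P1 in T12 (1 call, highest other 3, reached by 9 splits). At T0, with 0 calls for the real groups, the 35 splits of each comparison tested nothing either, and their highest others were 2, 6 and 3. Without F_P1 fish 6 the real counts and highest others were 841 and 69, 138 and 671, and 1303 and 1310 at P1, and 593 and 1594, and 433 and 304 at P2, each reached by at most 3 of 100 splits. Fish were the units of these splits, so with 2 tanks per regime they cannot tell regime from tank. Their shares were not adjusted over the comparisons. They also say nothing on the scan day of the H fish at P1.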
